A study of Mus musculus with 2 samples.

How the data were processed

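Gastrocnemius muscle was taken from 4-day-old male B6CASTF1/J mice, and long-read RNA sequencing was run on 1 library per replicate with 2 µg of total RNA each, per the labels. The series has 1 group of 2 biological replicates. Their labels give separate biosamples but 1 shared donor entry, so they do not settle whether the replicates are 2 mice. The libraries are treated here as coming from 2 mice, and every value for n = 2 mice rests on that assumption. The labels name an ERCC spike-in mix and a SIRV spike-in set, and only ERCC spike-ins were analysed here.

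The deposited transcript tables give, per library, the raw count of reads assigned to each transcript model, with the gene and the transcript class in TALON format, per the file headers. Each table has a transcript model with exon coordinates on mouse genome mm10, and annotated models carry GENCODE M21 identifiers, per the readme beside the files. The sequencing platform, the aligner and the tool versions of the authors' processing are not given in the sources used here. The classes are Known (annotated), ISM (part of an annotated intron chain), NIC (annotated splice sites in a combination outside the annotation), NNC (at least 1 splice site outside the annotation), genomic, antisense and intergenic. Identifiers of unannotated models differ between the libraries, so models were matched by chromosome, strand and intron chain. A transcript called unannotated here is outside GENCODE M21.

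Replicate 1 held 1066347 counts and replicate 2 held 1100253. Counts on annotated mouse genes were summed per gene over all classes and scaled to CPM with the library's annotated mouse gene counts as the denominator. Counts on unannotated loci (3.88% and 5.36% of all counts in replicates 1 and 2) and on spike-ins (2.47% and 1.37%) stayed out of library sizes and gene tests. For 20 gene symbols with more than 1 identifier, each identifier was kept apart. A count of 0 allows up to 3 counts at the 95% level, and fold differences against 0 counts use that floor.

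Values are the mean ± SD over n = 2 mice, with exact Clopper-Pearson 95% intervals for the share in a single library. No test of the group was made, since with 2 mice a sign-flip permutation has a smallest two-sided p of 0.5. Library was compared with library by a two-sided Fisher's exact test per gene with at least 10 counts in sum, with Benjamini-Hochberg adjustment at 0.05. This test holds counting error only, and it compares 2 libraries and not 2 conditions. For each of 28 gene lists fixed beforehand, the median log2 ratio with a prior count of 0.5 was placed among 10000 random lists of the same size drawn within 20 expression bins, and the called genes were counted over all genes tested and again adjusted over the list alone. The biological coefficient of variation (BCV) came from edgeR 4.0.16 with an intercept-only design. Leading transcripts were compared over genes with at least 20 counts on Known, NIC and NNC transcripts in each library. The share of a leading transcript is taken over those counts, without the ISM and genomic counts of the gene. Cassette exon inclusion is the count on models with the exact internal exon over that count plus the count on models whose intron spans it, for exons with at least 20 such counts in each library. Exons at 5 to 95% in both libraries are called intermediate. Both isoform comparisons used the same exact test and adjustment.

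Genes were named by a rule written before the data were seen. It took the highest members of each list, the lowest member and those without counts, the 20 genes with the highest mean CPM, and the 10 genes per direction with the largest ratios (prior count 0.5) among called genes with at least 50 counts in sum. It also took the members of a splicing list, the 10 highest genes with an unannotated leading transcript, the 10 smallest adjusted p for leading transcripts and for exons, and 5 genes that check the sex label. Other list members named in the text, such as Ttn, Neb, Chrng, Chrne and Gapdh, were chosen after their values were seen. Some list members that the rule names are not reported here. The pseudogenes and the unannotated loci were also chosen after their values were seen, and the added skin, hair and melanocyte markers after those of the epidermal list but before their own.

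Alternatives tried were TMM from edgeR and size factors from DESeq2 1.42.0, other count minimums, other pseudocounts and prior counts, narrower sets of transcript classes, preset BCVs of 0.1 and 0.2 in edgeR's exact test, a fold minimum, a denominator without mitochondrially encoded genes, matching of splice sites within 5 bases, and each replicate on its own. A gene length taken from the annotation, a scaling by transcript length, random lists matched on length, shared intron chains given to 1 gene, and classes taken from either library were chosen after seeing the data. The scaling and the matched lists used the longest annotated transcript detected. Pseudogenes were aligned to parent genes with minimap2 2.31 under the asm20 preset. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.

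On simulated data with 200 of 11027 genes changed, Fisher's exact test found 13.4%, 34.3% and 77.3% of those changed 1.5-fold, 2-fold and 4-fold, and 42.9%, 75.0% and 100% of those with at least 100 counts. It called 8 unchanged genes, and 0 genes in a simulation without change. With no gene changed but a coefficient of variation of 0.2 between libraries it called 1101 genes. A simulated BCV of 0.1 was recovered as 0.0999 and one of 0.2 as 0.204. Of random lists of 15 genes, 5.50% fell outside the central 95%, and 99.0% of lists shifted by 0.5 fell above it. Leading shares lowered by 20 points were found for 39.5% of 200 genes and 85.5% of the 55 with at least 100 counts. Exon inclusion raised by 20 points was found for 84.5% of 200 exons, with 4 of the unchanged exons among 999 called. These exons were simulated with more counts than the minimum of 20, and only 905 of the 1991 real intermediate exons reached 50 in each library. The 84.5% thus does not hold for real exons near the minimum. Depth sets the precision of 1 library only, and 62.8% of the transcript models in each library rest on a single count.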

Results

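Each of the 2 gastrocnemius muscles, the large fast muscle of the calf, gave 1 library of long reads. Counts on annotated mouse genes came to 998659 (93.7%) in replicate 1 and 1026257 (93.3%) in replicate 2. They covered 15526 and 16344 genes, 14011 of them in both libraries, 1515 in replicate 1 only and 2333 in replicate 2 only. Protein-coding genes held 97.6% and 97.4% of these counts, processed pseudogenes 1.06 ± 0.0859% (mean ± SD, n = 2) and lincRNAs 0.781 ± 0.0386%. The libraries matched the male label. Xist, the RNA that silences an X chromosome in females, had 0 counts in both, and the Y-linked genes Ddx3y (57 and 58 counts), Eif2s3y (72 and 70), Uty (6 and 16) and Kdm5d (2 and 4) were counted in each.

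Acta1, the skeletal muscle actin, had the highest level of all genes at 57496 ± 9033 CPM (n = 2), followed by Atp2a1, the calcium pump of fast muscle, at 36167 ± 14529. Ckm, the muscle creatine kinase, stood at 25633 ± 2856, Col3a1, a fibrillar collagen, at 18523 ± 4523, and Tnnc2, the calcium sensor of fast thin filaments, at 13480 ± 3348. Col1a1, the main collagen of tendon and bone, reached 9654 ± 4040. Then came Tpm1 (8190 ± 580), Mylpf (8093 ± 1175), Myl1 (7485 ± 1637) and Car3, a carbonic anhydrase (6555 ± 2409). They were followed by Eno3 (6288 ± 730), Aldoa (5788 ± 268), Slc25a4 (5590 ± 828), Myh8 (5449 ± 1845), Ldha (5102 ± 405), the imprinted RNA H19 (4808 ± 366), Itm2a (4654 ± 602), Des (4554 ± 781), Tpm2 (4394 ± 48.0) and Atp5b (3986 ± 99.2). These 20 genes held 24.2 ± 0.342% of the counts.

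The most counted myosin heavy chain gene of this muscle was the perinatal one. The shares below are of the counts on the Myh genes of the developmental, adult fast, and slow or other lists. Myh genes outside these lists, such as Myh11 of the mural list, are left out. Myh8, the perinatal fast form, gave 58.8 ± 1.57% (n = 2), and Myh3, the embryonic form, gave 8.51 ± 2.21%. Of the adult fast forms, Myh4 (the IIB chain) gave 15.1 ± 6.01%, Myh1 (IIX) 6.34 ± 0.114% and Myh2 (IIA) 1.47 ± 0.0486%, while Myh7, the slow chain, gave 9.27 ± 2.21%. Together Myh8 and Myh3 made up 67.3 ± 3.78%, with 64.6% of 11693 counts in replicate 1 and 70.0% of 7101 in replicate 2. In CPM, Myh8 stood at 5449 ± 1845, Myh4 at 1506 ± 1070, Myh7 at 826 ± 108, Myh3 at 755 ± 82.3, Myh1 at 589 ± 204 and Myh2 at 138 ± 54.3. The counts in replicates 1 and 2 were 33 and 15 for Myh14, 19 and 12 for Myh7b, 14 and 9 for Myh6, and 2 and 1 for Myh13, and Myh15 had none. Myh3 (11:67078300–67102291), Myh4 (11:67238029–67260446) and Myh8 (11:67277124–67308634) lie close together. Most Myh8 reads matched only part of its annotated exon chain, so with Known, NIC and NNC transcripts alone its level was 1615 CPM. Its share was then 34.8 ± 2.33%, still the highest, ahead of Myh4 at 20.7 ± 9.62%, and Myh8 and Myh3 together held 49.7%.

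**Figure D1:**
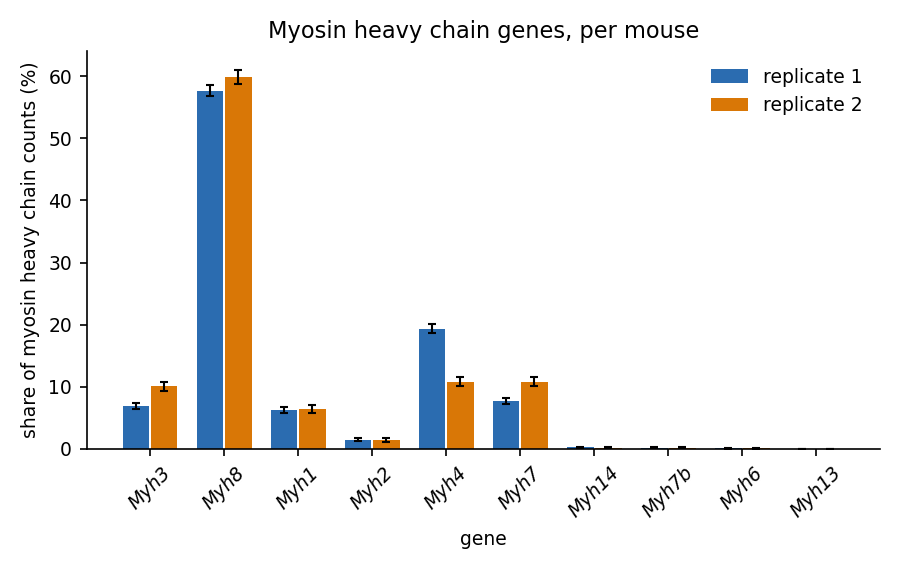
Share of the counts on the genes of the myosin heavy chain lists held by each gene in each mouse, with exact 95% intervals of counting error. Myh8 held 58.8 ± 1.57% (mean ± SD, n = 2).

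The adult fast list of contractile and calcium genes held 12.8 ± 0.0394% of the counts (n = 2), with Acta1 and Atp2a1 highest and Tnnt3, the fast troponin T, lowest at 429 ± 112 CPM, beside 434 ± 199 for the slow troponin T gene Tnnt1 of the slow fibre list. Tnni2, the fast troponin I, stood at 1409 ± 95.6 CPM. The fetal, slow or cardiac list held 0.306 ± 0.0408%. Its highest members were Casq2, the slow and cardiac calcium buffer (916 ± 105 CPM), Actc1, the cardiac actin also made in fetal muscle (757 ± 159), Tnnc1 (452 ± 199) and the embryonic light chain Myl4 (359 ± 149). Tnnt2, the cardiac troponin T, was lowest at 20.7 ± 2.39, and cardiac Tnni3 had no counts. The slow fibre list held 0.356 ± 0.0631%, from Myh7 (826 ± 108) and Tpm3 (772 ± 223) down to Myl2, the slow regulatory light chain (81.9 ± 12.4). With Known, NIC and NNC transcripts alone, the levels were 186 CPM for Tnnt3 and 5.11 for Tnnt2. For Tnni2 the mean of 669 CPM describes neither library (1093 and 76 such counts), since its leading structure was classed NIC in replicate 1 and ISM in replicate 2. In all, 47 of 269 named levels were over 1.5-fold lower with these classes alone, among them those of Myh2, Tnnt1, Pdgfra and Fabp4.

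Sarcomere and costamere genes held 3.31 ± 0.457% of the counts (n = 2). Highest were Tpm1 (8190 ± 580 CPM), the intermediate filament gene Des (4554 ± 781), Tpm2 (4394 ± 48.0) and Actn2, which anchors thin filaments at the Z-disc (3837 ± 652), and Mybph was lowest (38.6 ± 4.93). The giant filament genes Ttn and Neb stood at 157 ± 1.63 and 72.5 ± 13.3 CPM. With Known, NIC and NNC transcripts alone these were 24.3 and 29.9, and Ldb3, a Z-disc gene, was 3.41 against 203. The excitation-contraction coupling list held 4.18 ± 1.48%, mostly from Atp2a1. Its next members were the calcium buffer Casq1 (3346 ± 287) and the triad gene Trdn (512 ± 57.2), and Ryr3, a calcium release channel, was lowest (12.3 ± 4.65). Ryr1, the main release channel of skeletal muscle, stood at 198 ± 15.7 CPM, or 33.5 without partial transcripts.

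Genes of the neuromuscular synapse held 0.0751 ± 0.00253% of the counts (n = 2). Chrna1, a subunit of both the fetal and the adult acetylcholine receptor, was highest at 221 ± 6.35 CPM, followed by Ache, which breaks down acetylcholine (129 ± 19.2), and Lrp4 was lowest (8.88 ± 1.23). The fetal subunit gene Chrng stood at 47.1 ± 31.2 CPM and the adult subunit gene Chrne at 18.8 ± 1.04. Myogenic regulators and fusion genes held 0.643 ± 0.0869%, with Des (4554 ± 781), the differentiation factor Myog (505 ± 76.2), Mef2c (416 ± 63.2) and Mef2d (164 ± 29.0) highest. Pax7, which marks muscle stem cells, was lowest with 8 and 2 counts, and Pax3 had none.

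Glycolysis and the nuclear genes of oxidative phosphorylation were both well covered, and the mitochondrially encoded genes were not. Glycolytic genes held 2.86 ± 0.0714% (n = 2), from the muscle enolase Eno3 (6288 ± 730 CPM), Aldoa (5788 ± 268), Ldha (5102 ± 405) and Pkm (3369 ± 630) down to the hexokinase Hk2 (37.2 ± 19.6). Gapdh itself had only 56 and 51 counts, while 20 processed pseudogenes closest to it held 3428 and 2996, so its level is uncertain. Nuclear genes of oxidative phosphorylation held 1.57 ± 0.0660%, from the ATP synthase genes Atp5b (3986 ± 99.2) and Atp5a1 (2715 ± 499) and the cytochrome oxidase gene Cox4i1 (1626 ± 544) down to Cox7a1 (61.6 ± 14.9). Mitochondrially encoded genes had only 295 counts in replicate 1 and 479 in replicate 2 (0.0381 ± 0.0121%). Highest were mt-Co1 (197 ± 59.7) and mt-Cytb (68.4 ± 25.9), mt-Rnr1 was lowest (1 and 0 counts), and mt-Nd3, mt-Nd4l, mt-Nd6 and mt-Atp8 had none. Ribosomal protein genes held 0.687 ± 0.156%, from Rplp0 (1259 ± 236), Rpl3 (884 ± 280) and Rpl4 (883 ± 123) down to Rpl10 (15.8 ± 1.70). Many of these have processed pseudogenes, so single members are uncertain.

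Imprinted and fetal growth genes held 1.44 ± 0.000477% of the counts (n = 2). H19 (4808 ± 366 CPM), the cell cycle inhibitor gene Cdkn1c (3814 ± 113), Dlk1, a preadipocyte and myoblast surface factor (2082 ± 128), and Mest (1625 ± 421) were highest. Igf2bp1 had 1 count in each library and Lin28b had none. Igf2, the fetal growth factor gene beside H19, stood at 375 ± 3.73 CPM, but at 40.3 with Known, NIC and NNC transcripts alone. Stress and immediate early genes, which respond to handling of the tissue, held only 0.0365 ± 0.000903%. Ier2 (84.9 ± 5.35) and Jun (58.0 ± 22.8) were highest, and Fosb was lowest with 1 count in replicate 1.

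Of the cell type lists, that of fibroblasts and matrix held the largest share, with 3.52 ± 0.871% of the counts (n = 2), from Col3a1 (18523 ± 4523 CPM), Col1a1 (9654 ± 4040), Sparc (2291 ± 163) and Col1a2 (1695 ± 33.4) down to Pdgfra, a receptor on mesenchymal progenitors (30.7 ± 3.38). Col1a2 came to 147 CPM with Known, NIC and NNC transcripts alone. The Schwann cell and nerve list held 0.251 ± 0.145%, from the myelin genes Pmp22 (1195 ± 638) and Mbp (647 ± 448) down to Ngfr (8 and 4 counts). The tendon list held 0.0779 ± 0.00381%, from Tnmd (275 ± 40.8) and Fmod (204 ± 16.5) to Mkx (5 counts in each library). The mural and smooth muscle list held 0.0671 ± 0.00346%, from Acta2 (322 ± 53.2) and Rgs5 (161 ± 24.1) to Myh11 (26.7 ± 6.10). The endothelial list held 0.0651 ± 0.00489%, from the tight junction gene Cldn5 (250 ± 51.0) and Egfl7 (97.6 ± 17.7) to Emcn (12.8 ± 3.94).

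Smaller shares came from blood, fat, immune, dividing and stem cells. The erythroid list held 0.0330 ± 0.0101% (n = 2), from the globin genes Hba-a1 (179 ± 39.8 CPM) and Hbb-bs (88.0 ± 46.5), whose near-identical copies make single members uncertain, to Alas2 (7.38 ± 3.35), and Slc4a1 and Hbb-y had no counts. The satellite cell list held 0.0268 ± 0.00610%, from Cdh15 (122 ± 26.8) and Chodl (92.1 ± 26.9) to Calcr (4 counts in each library). The adipocyte list held 0.0260 ± 0.0156%, from the fatty acid carrier gene Fabp4 (139 ± 63.0) and Adipoq (51.5 ± 38.8) to Lep (1 and 5 counts), and Ucp1 had none. The macrophage and leukocyte list held 0.0256 ± 0.00551%, from Csf1r (57.7 ± 3.78) and Lyz2 (49.8 ± 8.12) to S100a8 (0 and 1 counts), and S100a9 had none. The list of proliferating cells held 0.0254 ± 0.00719%, from Ccnb1 (55.6 ± 17.8) and Cdk1 (49.7 ± 15.1) to Cenpf (3 and 4 counts). The bone and cartilage list held 0.00450 ± 0.000995%, from Col2a1 (30.2 ± 6.87) to Sox9 (1 count in each library), and Bglap, Ibsp and Sp7 had none. The epidermal list held 0.0460 ± 0.0645%, with 4 counts in replicate 1 and 940 in replicate 2.

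Between the 2 mice, the largest differences were in genes of the skin. Krt10, a keratin of the upper epidermis (11:99385254–99389364), had 4 counts in replicate 1 and 323 in replicate 2, which is 78.6-fold higher (log2 ratio 6.30, 95% interval 4.93 to 8.18). Lor, which builds the cornified envelope, and the keratin gene Krt1 had 0 counts in replicate 1 and 191 and 190 in replicate 2, at least 62.0-fold and 61.6-fold higher against a floor of 3 counts in replicate 1. Myelin genes were also higher in replicate 2, by 2.93-fold for Mbp and 2.21-fold for Pmp22. Lower in replicate 2 were the myosin gene Myh4 (3.02-fold), Col1a1 (1.84-fold) and Atp2a1 (1.79-fold).

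By a two-sided Fisher's exact test, 1074 of 11027 genes (9.74%) differed between the libraries at an adjusted p under 0.05. Of these 579 (53.9%) were higher in replicate 2 and 495 lower. The test counts sampling error only, and a simulation with no gene changed but a coefficient of variation of 0.2 gave 1101 calls, so a spread of that size between mice would be enough for as many calls. The BCV between the mice was 0.211. When edgeR's exact test was given a preset BCV of 0.1, 172 genes passed (125 higher, 72.7%), and with 0.2 only 56 did (51 higher, 91.1%). Requiring an absolute log2 ratio of at least 1 left 347. The balance of directions moved with the scaling. An exact binomial test called 1062 genes with TMM (607 higher, 455 lower) and 1029 with DESeq2 size factors (630 higher, 399 lower). Across the 11027 genes, levels in the libraries correlated at r = 0.912 (Pearson) and rho = 0.919 (Spearman).

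The 10 largest ratios in each direction, ranked with a prior count of 0.5 among called genes with at least 50 counts in sum, all had an adjusted Fisher's exact p under 0.05. Krt10 ranked below these 10. After Lor and Krt1 came the hair root sheath gene Krt71 (131 counts in replicate 2), the basal keratin gene Krt14 (130), Krt17 (94), Krt15 (71), the epidermal protease gene Asprv1 (69), Krt27 (61), Krt87 (54) and Perp (51). All had 0 counts in replicate 1, and against the same floor they were at least 42.5-fold (Krt71) to 16.5-fold (Perp) higher. Krt5, a further member of the epidermal list, had 0 and 35 counts. In the other direction Pitpna had 164 and 5 counts (33.7-fold lower), the imprinted retrotransposon-derived gene Rtl1 251 and 36 (7.16-fold), Mum1l1 49 and 11 (4.58-fold), Vcp-rs 270 and 75 (3.70-fold) and Ehmt1 63 and 18 (3.60-fold). They were followed by Cbfa2t3 with 41 and 13 counts (3.24-fold), Ptcd1 49 and 16 (3.15-fold), Supt20 54 and 18 (3.08-fold), Myh4 2260 and 769 (3.02-fold) and Rbm5 60 and 21 (2.94-fold). Of these, Mum1l1, Ehmt1, Cbfa2t3, Ptcd1, Supt20 and Rbm5 did not pass at a BCV of 0.2, and Rtl1 did not pass with Known, NIC and NNC transcripts alone. Counted under any identifier, however, the Pitpna structures (11:75588097–75628804) had 164 and 155 counts. Beside Rtl1 (12:109589193–109600330), 203 replicate 1 counts were on a model named Rtl1 at 12:109599809–109603182 and 244 replicate 2 counts on an unannotated locus at 12:109600820–109602914, and with that locus the counts were 251 and 280. Vcp-rs is a processed pseudogene 99.05% identical to Vcp over the aligned part, so its reads may belong to Vcp.

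Among the muscle lists, the adult fast myosin, slow and other myosin, sarcomere and myogenic regulator lists lay below the central 95% of random lists, and the slow fibre, oxidative phosphorylation, mitochondrially encoded and ribosomal lists above it. Against random lists also matched on transcript length, chosen after seeing the data, the slow and other myosin, slow fibre, nuclear oxidative phosphorylation and ribosomal lists lay inside it. That matching left out genes without a detected annotated transcript, such as Tnnt1 and Tnni1 of the slow fibre list (log2 ratios 0.97 and 0.71). The move of the slow fibre list thus cannot be put down to length alone. For the adult fast myosins the median log2 ratio was −0.82 (−0.83 with zeros at the floor), at percentile 0.125 of random lists, and all 3 genes were called lower, also when adjusted over the list alone. For the developmental myosins it was −0.46 (percentile 4.17), with both genes called lower (Myh8 by −0.70, Myh3 by −0.22), also over the list alone. For slow and other myosins it was −0.67 (−0.69 at the floor; 1.92), with 1 of 4 tested genes lower (Myh7, −0.27) and 2 when adjusted over the list alone. For the sarcomere list it was −0.35 (0.02), with 1 of 20 genes higher (Cryab, a small heat shock protein, 0.55) and 11 lower, such as Nrap (−0.81), Mybpc1 (−0.71) and Actn2 (−0.35), and 1 and 12 when adjusted over the list alone. For excitation-contraction coupling it was −0.10 (21.1), with 1 higher (Sln, a calcium pump inhibitor, 0.44) and 4 lower, among them Cacna1s (−0.92) and Jph1 (−0.91), and 2 and 4 when adjusted over the list alone.

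For the adult fast contractile genes the median was 0.31 (percentile 92.7), with 5 of 8 higher (Tnnc2 by 0.51) and 2 lower (Atp2a1 by −0.84), and 5 and 3 when adjusted over the list alone. For the fetal forms it was 0.43 (97.4), with 4 of 7 higher (Tnnc1 by 0.93, Myl4 by 0.87, Tnni1 by 0.71 and Actc1 by 0.43) and 2 lower (Atp2a2 by −0.57), and the same counts over the list alone. For slow fibre genes it was 0.59 (99.98), with 6 of 9 higher (Tnnt1 by 0.97) and 2 lower, also over the list alone. For nuclear oxidative phosphorylation genes it was 0.31 (98.8), with 10 of 19 higher (Cox6a1 by 1.29, Cox4i1 by 0.70) and 2 lower (Sdha by −0.40, Atp5a1 by −0.38), also over the list alone. For mitochondrially encoded genes it was 0.89 (0.91 at the floor; 99.99), with mt-Co1 (0.63) and mt-Cytb (0.79) higher of 8 tested, also over the list alone. For ribosomal proteins it was 0.39 (99.9), with 12 of 18 higher (Rps6 by 0.83), and 14 when adjusted over the list alone.

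Glycolysis had a median of 0.02 (percentile 40.5), with 4 of 15 higher (Pgam2 by 0.52) and 5 lower (Hk2 by −1.13, Pkm by −0.38), and 5 and 5 when adjusted over the list alone. Myogenic regulators had −0.33 (1.11), with Myog higher (0.31), 2 of 16 lower (Mef2c by −0.31), and 2 and 4 when adjusted over the list alone. Synapse genes had 0.20 (85.8), with the fetal receptor gene Chrng higher (25 and 71 counts, 1.47) and Chrnd lower (−0.76) of 11, also over the list alone. Imprinted genes had 0.03 (50.7), with Mest (0.53) and Ndn (0.38) higher and H19 (−0.16) and Meg3 (−0.32) lower of 15 tested, and 3 and 2 when adjusted over the list alone. Stress genes had 0.18 (82.5), with Mt2 higher (6 and 24 counts, 1.96) and Jun lower (−0.82) of 12, also over the list alone.

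Among the cell types, skin, fat and nerve genes stood out. All 6 epidermal genes were called higher, also over the list alone, with a median of 7.55 (5.67 at the floor; percentile 100). All 4 tested adipocyte genes were higher, also over the list alone (median 1.69, or 1.71 at the floor; 99.99), such as Plin1, which coats lipid droplets, with 7 and 33 counts (4.59-fold) and Adipoq with 24 and 81. Of 8 Schwann genes 4 were higher, and 5 when adjusted over the list alone (1.11, or 1.12 at the floor; percentile 100). Of 5 tested erythroid genes Hba-a1 (0.46) and Hbb-bs (1.13) were higher, also over the list alone (median 0.62, or 0.63 at the floor; 98.7). Of 9 tested proliferation genes Stmn1, which destabilises microtubules (25 and 55 counts), was higher, also over the list alone (0.62, or 0.63 at the floor; 99.6). Of 12 fibroblast genes 3 were higher (Lum by 0.77, Dcn by 0.21 and Sparc by 0.15) and 6 lower (Col1a1 by −0.88, Postn by −0.60), also over the list alone (−0.40; 0.11).

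The other cell type lists lay within the central 95%. The macrophage list had a median of 0.34 (0.35 at the floor; percentile 93.9), with C1qa (27 and 58 counts) higher of 8 tested, also over the list alone. The endothelial list had 0.02 (55.2), with Cldn5 (0.42) higher of 8, also over the list alone. The mural list had −0.04 (43.4), although Tagln (1.17) and Acta2 (0.34) were higher of 7, also over the list alone. The tendon list had 0.13 (70.0), with 0 of 6 called, and 3 higher and 1 lower when adjusted over the list alone. The satellite cell list had −0.36 (−0.37 at the floor; 10.8), with 0 of 6 tested called, and 2 lower when adjusted over the list alone. The bone list had −0.62 (−0.64 at the floor; 9.41), with 0 of 2 tested called, also over the list alone. In all, 14 of 28 lists lay outside the central 95% of random lists, and 8 did when the random lists were also matched on transcript length. The slow and other myosin (percentile 8.10), slow fibre (93.4), oxidative phosphorylation (74.6), ribosomal (79.0), fibroblast (4.88) and erythroid (88.8) lists then lay inside. The slow fibre list was scored there without Tnnt1 and Tnni1.

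**Figure D2:**
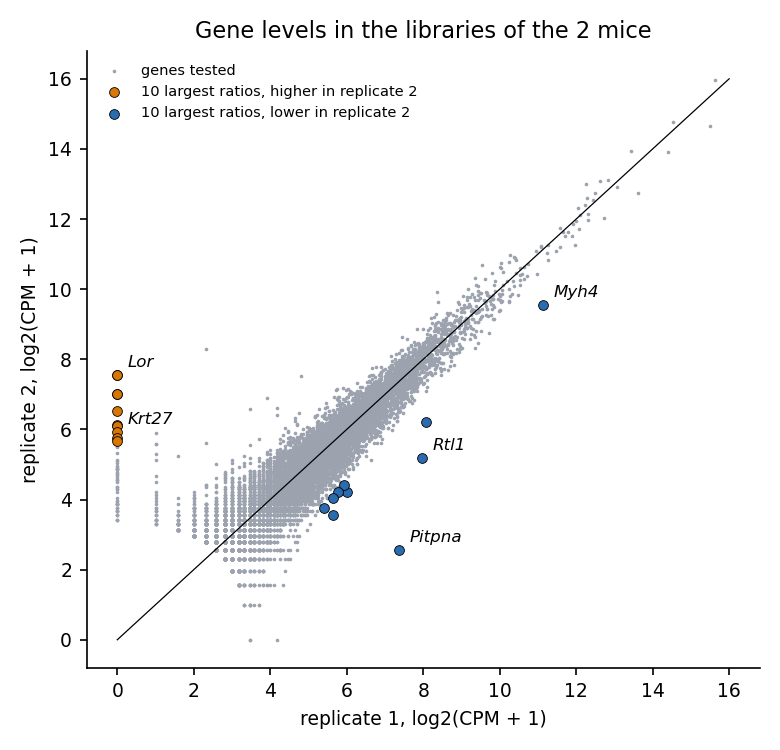
Level of each tested gene in the libraries of the 2 mice, with the 10 largest ratios in each direction marked among 11027 genes.

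Most counts fell on annotated transcripts. Known transcripts held 71.1 ± 0.934% of all counts (n = 2), ISM 8.93 ± 0.293%, NIC 6.47 ± 0.532%, NNC 6.08 ± 1.35%, antisense 4.02 ± 0.930%, genomic 3.02 ± 0.248% and intergenic 0.402 ± 0.0637%. On the 44 ERCC spike-ins counted in each library, 0 of 26345 and 0 of 15034 counts fell into the ISM, NIC, NNC or genomic class, below 0.0114% and 0.0200% at the 95% level. On mouse genes 26.0 ± 2.05% did. The spike-ins have a single exon, so they say nothing of errors at splice sites, and on mouse genes with a single exon the share was 1.25% and 1.27%.

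**Figure D3:**
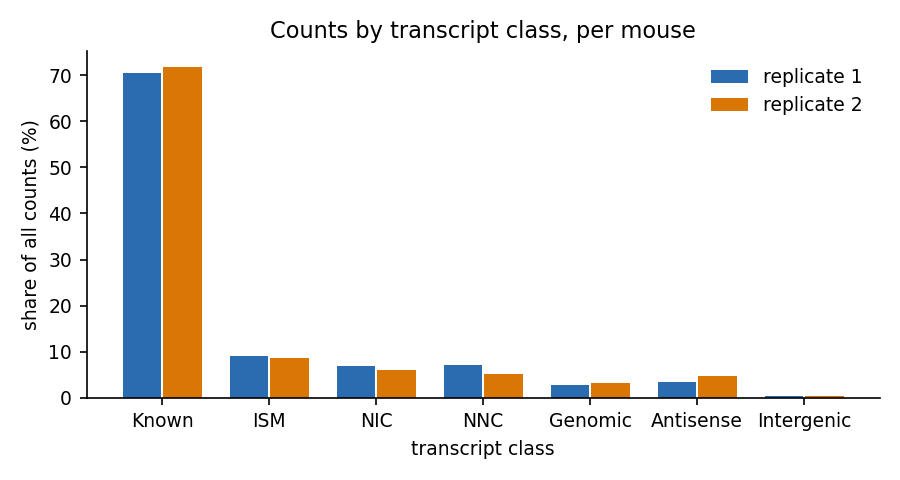
Share of all counts in each transcript class in each mouse. Known transcripts held 71.1 ± 0.934% (mean ± SD, n = 2).

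Partial transcripts were more frequent on genes with long transcripts, taking the longest annotated transcript detected as the length of a gene. Genes under 1 kb had 6.06 ± 0.272% of their counts in class ISM (n = 2; 1849 genes), those of 1 to 2 kb 5.39 ± 0.0421%, those of 2 to 4 kb 8.51 ± 0.0727%, those of 4 to 8 kb 17.5 ± 0.264% and those over 8 kb 24.2 ± 1.40% (385 genes). That length understates genes whose longest annotated transcript was not detected. Examples are Atp2a1 (681 nt against 3477 in the annotation), Neb (1000 against 22489) and Ttn (3513 against 106824). In Atp2a1 the leading structure of 3443 nt was unannotated and did not enter that length. With the longest transcript in the annotation, chosen after seeing the data, ISM held 4.58% under 1 kb and 27.0% over 8 kb. The ratio between the libraries also went with length. Its median log2 was 0.43 for genes under 1 kb, 0.29 for 1 to 2 kb, −0.08 for 2 to 4 kb, −0.29 for 4 to 8 kb and −0.26 over 8 kb. Long genes such as Myh8, Col1a1, Mybpc1 and Cacna1s were on the lower side, and short ones such as Tnnc2, Rps6 and Myl4 on the higher. Not every gene followed the trend, with the short Tcap (948 nt) at −0.46 and the long Trdn (4149 nt) at 0.23. When the libraries were scaled by transcript length, chosen after seeing the data, 650 genes differed, and 482 of them were among the 1074. This scaling used the longest annotated transcript detected, so Atp2a1 was scaled as a short gene. Genes without such a transcript were not scaled.

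**Figure D4:**
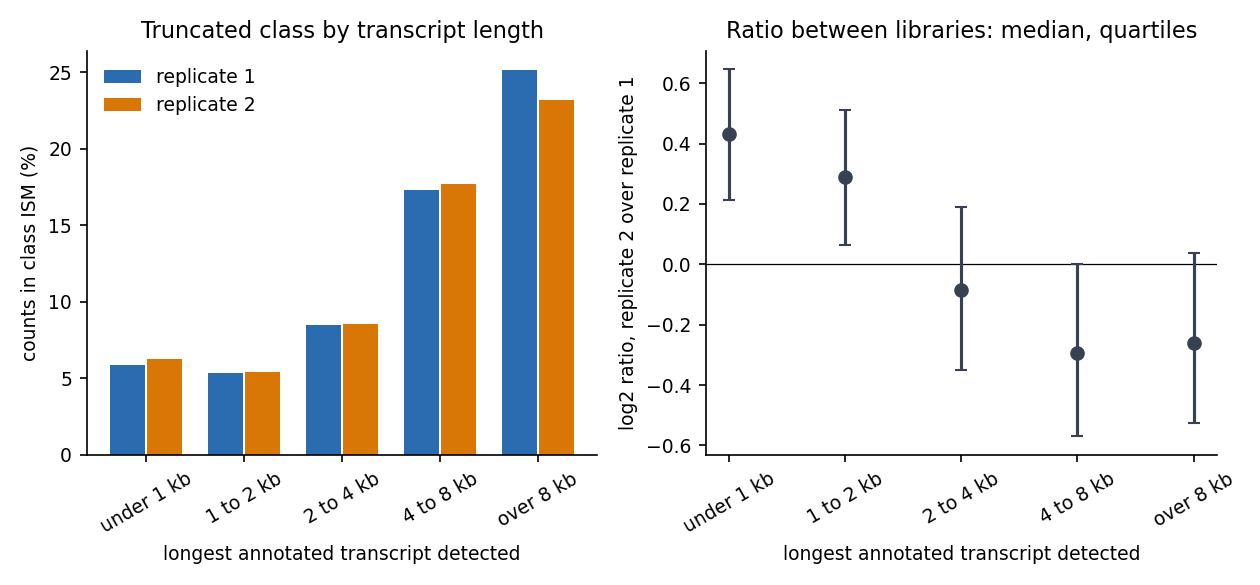
Share of counts on partial transcripts (left) and median log2 ratio between the libraries with quartiles (right), by transcript length. ISM held 24.2 ± 1.40% of counts on genes over 8 kb.

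The libraries mostly had the same leading transcript per gene. Shares are of a gene's counts on Known, NIC and NNC transcripts, without its ISM and genomic counts. Tpm1, which winds along the thin filament, had 97.8% and 97.2% in replicates 1 and 2 on Tpm1-205. Tpm2 had 95.8 ± 0.227% (n = 2) on Tpm2-202, and Tmem38a, a channel of the sarcoplasmic reticulum, had 91.8 ± 1.26% on Tmem38a-201. Atp2a1 led with an unannotated structure of 21 exons (7:126445858–126463108), with 81.3% and 78.6% of 43318 and 24502 such counts. Mef2c was spread widely, with 23.6 ± 0.568% on Mef2c-228. Over all genes with enough counts, 5105 of 5351 (95.4%) had the same leader in both libraries. Known transcripts led in 5090, NIC in 193 and NNC in 68. The median leader held 86.4% of a gene's Known, NIC and NNC counts among 8 structures. Among these counts the median gene thus had 1 dominant transcript.

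Unannotated structures led 10 of the more highly expressed genes in both libraries. After Atp2a1 they were Srl, a calcium buffer of the sarcoplasmic reticulum (75.5 ± 2.57%, n = 2), Col1a2 (33.5 ± 3.08%), Oaz1, which limits polyamine synthesis (96.4 ± 0.128%), Myh4 (49.2 ± 2.94%), Bin1, which shapes T-tubules (63.6 ± 1.36%), Eno1 (79.4 ± 5.97%), Meg3 (20.5 ± 3.00%), Ndrg2 (52.5 ± 0.564%) and Hnrnpk (50.3 ± 0.0951%). The leaders of Atp2a1, Col1a2, Myh4 and Bin1 were classed NNC, with a splice site outside the annotation. For Col1a2 the share rests on 41 of 131 and 46 of 129 Known, NIC and NNC counts, beside 1716 and 1715 counts in all classes. In total the libraries held 44549 and 44503 NIC or NNC structures, and 11859 were in both (26.6% of those in replicate 1). The shared ones held 73.5% and 69.4% of the NIC and NNC counts. Of the shared structures, 1228 were classed NIC in 1 library and NNC in the other, so that label is uncertain for them. Of Known transcripts with several exons, 15062 were in both, which is 82.3% and 79.9% of those in each library. With at least 5 counts in each library, 1526 unannotated structures were shared.

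Of the splicing list, 40 of 49 genes had enough counts, and 34 had the same leader. Pkm, the pyruvate kinase gene, led with Pkm-202 at 84.2 ± 1.59% (n = 2), Capzb with Capzb-203 at 76.0 ± 0.329%, Tpm3 with Tpm3-205 at 72.2 ± 3.42%, Fhl1 with Fhl1-204 at 66.2 ± 6.33%, Myl1 with Myl1-202 at 63.9 ± 3.15% and Mybpc1 with Mybpc1-202 at 31.3 ± 2.59%. Further annotated leaders were those of Atp5c1 (87.7 ± 2.45%), Rtn4 (81.4 ± 1.49%), Igf1 (81.0 ± 2.99%), Ank1 (79.0 ± 1.64%), Slc25a3 (77.1 ± 2.60%), Pdlim3 (76.6 ± 3.07%), Cacna1s (57.9 ± 9.95%), Nfix (46.7 ± 3.87%), Camk2g (38.8 ± 5.71%), Mef2a (34.5 ± 3.64%), Postn (32.9 ± 1.09%), Nrap (25.3 ± 5.62%) and Neb (13.9 ± 6.01%). Unannotated structures led Pdlim5 (78.7 ± 2.90%), Pdlim7 (61.1 ± 9.48%), Kif1b (52.8 ± 5.32%), Ttn (39.6 ± 4.59%), Tnnt1 (27.7% and 31.2%), Mef2d (28.7 ± 10.5%), Tnnt3 (26.4 ± 6.61%), Camk2d (24.9 ± 2.54%) and Fn1 (23.3 ± 2.86%). The Ttn leader had 5 exons and 2678 nt, with 8 of 22 and 9 of 21 counts. The annotated Neb leader had 10 exons and 1000 nt, with 4 of 22 and 3 of 31. Both are far shorter than the longest annotated transcripts (106824 and 22489 nt), so they say little of the full transcripts. Camk2b, Dtna, Fxr1, Mbnl2 and Trim55 were among the listed genes with different leaders. Clcn1, Fhod3, Ldb3, Mbnl1, Ncam1, Ppp1r12b, Ryr1, Sorbs2 and Tnnt2 were below the minimum of 20 counts on Known, NIC and NNC transcripts.

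The leading share differed between the libraries for 25 of 5047 genes (two-sided Fisher's exact test, adjusted p under 0.05), 12 higher and 13 lower in replicate 2. Atp2a1 had 81.3% and 78.6% (adjusted p 5.91e-14), the collagen gene Col3a1 96.7% and 95.0%, the myelin gene Pmp22 58.9% and 42.3%, Aldoa a share 6.24 points higher in replicate 2 (−0.302 points with Known transcripts only), and Acta1 98.2% and 98.7%. Fhl1 (61.7% and 70.6%) and Myl1 (61.7% and 66.2%) were the other called members of the splicing list. Of the 10 genes with the smallest adjusted p, those with larger differences, Tnni2 (91.9% and 0%), Vdac3 (0% and 76.9%), Csnk1g2 (0% and 74.0%), Ywhae (97.7% and 63.0%) and Tmem65 (58.4% and 92.2%), rest on the transcript class each library was given. Counting a structure where either library has it as Known, NIC or NNC, chosen after seeing the data, put the differences at 0.224 points for Tnni2, −3.26 for Vdac3, 2.26 for Csnk1g2, −3.84 for Ywhae and −9.60 for Tmem65, and left 15 of the 25 genes called. With ISM transcripts included 90 genes were called, and with Known transcripts only 5.

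Exons with a known form in young or growing tissue were included to different degrees. The 42-nt exon near the end of Atp2a1 (7:126446545–126446586), whose skipping gives the neonatal calcium pump, was included in 17.1 ± 2.02% of counts (n = 2). The 57-nt exon of the calcium channel gene Cacna1s (1:136104570–136104626), skipped in the embryonic form, was included in 67.6 ± 10.7%. In Pkm the exon of the fetal and proliferative M2 form (9:59675568–59675734) was included in 11.6 ± 1.47%, and the exon of the adult muscle M1 form (9:59675029–59675195) in 88.5 ± 1.66%. In Fn1 the extra domain A exon (1:71603660–71603929), typical of growing tissue, was included in 40.8 ± 2.93%. In Bin1 a 72-nt exon was included in 72.5 ± 0.909%.

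Of 16789 cassette exons measured, 1991 in 1185 genes were intermediate in both libraries. Of these, 1771 (89.0%) were annotated, and of the 1347 wholly coding ones 877 (65.1%) kept the reading frame. Their median difference between the libraries was 4.45 points. Of the splicing list, 36 genes had such an exon by pooled inclusion. The values below are for 1 exon per gene, the one with the most informative counts, and other exons of the same genes differ from them. Myl1, with its alternative starts, had 31.7 ± 3.26% (n = 2) for a 28-nt exon (1:66934246–66934273). Inclusion was above 80% for the exons of Ank1 (94.6 ± 1.34%), Tmem38a (93.9 ± 0.153%), Pdlim5 (91.3 ± 3.66%), Nrap (90.1 ± 1.41%), Trim55 (88.1 ± 0.783%), Ttn (86.3% and 86.6%), Mef2a (84.0% and 85.3%), Fxr1 (82.0 ± 2.87%) and Neb (81.5 ± 6.69%). It was lower for those of Pdlim3 (79.4 ± 1.94%), Capzb (78.5 ± 0.271%), Tpm3 (78.3 ± 2.75%), Mef2d (77.9 ± 10.3%), Kif1b (70.5 ± 6.71%), Camk2d (51.0 ± 3.81%), Tnnt1 (49.1 ± 0.442%), Mbnl2 (45.3 ± 10.0%) and Tnnt3 (43.9 ± 6.55%). It was lower still for those of Camk2g (37.6 ± 7.07%), Postn (30.4 ± 3.14%), Pdlim7 (29.0 ± 8.06%), Mef2c (26.7 ± 6.72%), Slc25a3 (17.8 ± 1.94%), Igf1 (15.7 ± 2.40%), Mybpc1 (14.2 ± 2.43%), Camk2b (13.4 ± 3.46%), Nfix (10.6 ± 3.17%) and Atp5c1 (10.1 ± 2.97%). The Tpm1 exon is outside the annotation and had few informative counts. It was at 4.55% in replicate 1 (1 count with it, 21 without) and 32.1% in replicate 2 (9 with it, 19 without).

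Between the libraries 10 exons in 7 genes differed, 6 higher and 4 lower in replicate 2 (two-sided Fisher's exact test, adjusted p under 0.05). With at least 50 counts in each library 15 exons were called, 6 higher and 9 lower. With Known, NIC and NNC transcripts only 14 were called, 8 higher and 6 lower. The Atp2a1 exon was at 15.7% and 18.5% (adjusted p 1.32e-18). In Myl1 the 28-nt exon was at 34.0% and 29.4% and a 25-nt exon (1:66934518–66934542) at 64.9% and 69.7%. In Mybpc1, which steadies thick filaments, a 54-nt exon (10:88537466–88537519) was at 27.5% and 34.3% and a 59-nt exon (10:88521277–88521335) at 12.5% and 15.9%. In Eno1 the exclusive exons were at 14.8% and 22.3% (4:150242122–150242180) and at 85.3% and 77.9% (4:150241767–150241825). A 1311-nt exon of Srl (16:4496405–4497715) was at 16.3% and 11.8%, a 96-nt exon of Sema6c (3:95171791–95171886) at 56.8% and 27.9%, and a 39-nt exon of Acss2 (2:155551190–155551228) at 29.4% and 69.6%. The Cacna1s exon (60.1% and 75.2%) did not pass at this depth (adjusted p 0.139, exact test).

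**Figure D5:**
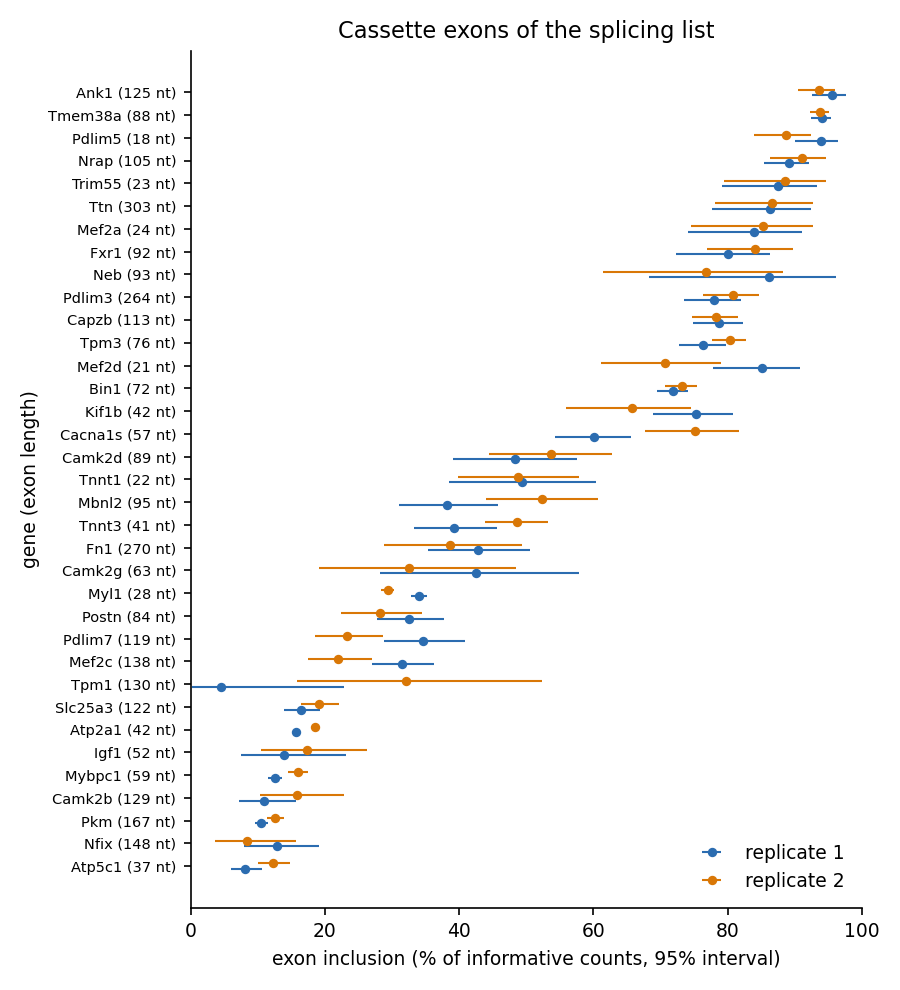
Inclusion of 1 cassette exon per gene, for genes of the splicing list named in the text, in each mouse, with exact 95% intervals of counting error. The Atp2a1 exon was at 17.1 ± 2.02% (mean ± SD, n = 2).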

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

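Some counts on unannotated loci were far above the 3 that a count of 0 allows, and all 3 loci below were chosen after their values were seen. The locus on chromosome 17 at 39843013–39848035 (minus strand) held 4001 counts in replicate 1 and 2890 in replicate 2, which is 0.375% and 0.263% of all counts. It lies opposite the annotated lincRNAs Gm26917 and Gm42418, on the strand of CT010467.1 and AY036118. The locus on chromosome 9 at 77656524–77660127 (minus strand), opposite Klhl31, held 809 and 1082 counts (0.0759% and 0.0983%). The locus on chromosome 1 at 93507854–93509733 (minus strand), opposite Sept2, held 383 and 671 counts (0.0359% and 0.0610%). No test was applied to these loci.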

How the results depend on the processing

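Settings marked as chosen after seeing the data were added late, and all others were fixed beforehand. A value is called the same when it moved by no more than 1 SD between the mice, and a count when it stayed within 1.5 times; correlations have no SD here and were never called the same. By this rule 22 of 42 alternatives to the main comparisons were the same. With Known, NIC and NNC transcripts only, the developmental myosin share was 49.7% (55.2% with Known transcripts only) against 67.3%, and the 20 highest genes held 25.7% against 24.2%. Against 1074 genes differing between the libraries, edgeR's exact test gave 172 at a BCV of 0.1 and 56 at 0.2, a fold minimum gave 347 and, chosen after seeing the data, scaling by transcript length gave 650. Lists outside the central 95% came to 8 against 14 when random lists were matched on length, also chosen after seeing the data. Pearson's r was 0.877 with a pseudocount of 0.1 and 0.930 without a filter, against 0.912. The Known share was 74.0% on nuclear genes alone against 71.1%. Unannotated structures in both libraries fell from 11859 to 1526 with at least 5 counts in each, and genes with the same leading transcript from 5105 of 5351 (95.4%) to 2583 of 2677 (96.5%) with at least 50 counts. Genes whose leading share differed came to 90 with ISM included, 5 with Known only and 15 with the class of either library (chosen after seeing the data), against 25. Intermediate exons came to 905 with at least 50 counts and 1293 between 10 and 90%, against 1991. Counts outside the Known class came to 23.0% on mouse genes with at least 100 counts against 26.0%. With gene length taken from the annotation, chosen after seeing the data, ISM held 27.0% over 8 kb against 24.2%. Leading share differences that turned sign were Tnni2 (0.224 points, class of either library), Ywhae (0.0443, Known only), Vdac3 (−3.49 with ISM, −3.26 with either class), Tmem65 (−9.10 and −9.60) and Aldoa (−0.302, Known only). With Known, NIC and NNC transcripts only, 94 of 269 levels of named genes moved by more than 1 SD and 175 did not. A denominator without mitochondrially encoded genes left all 269 within 1 SD. Those genes held only 0.0381 ± 0.0121% of the counts, so this setting could hardly move a level. For the 10 largest log2 ratios in each direction, the same meant an unchanged sign and an adjusted p still under 0.05. By that rule 191 of 200 values were the same and 9 weaker. The fold minimum could not change a call, since these genes were chosen for their ratios. At a preset BCV of 0.2, 14 were the same and 6 weaker. Each mouse on its own gave a developmental myosin share of 64.6% or 70.0%, always within 1 SD of a mean of 2.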

Other observations

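The tests of the skin explanations and the spike-in test were written before their results were seen; the tests of partial transcripts, of Myh4 and of single genes were chosen after. No biological explanation was tested, since the design has 1 group. Beside the planned results, several processed pseudogenes held more counts than their parent Gapdh, and others came near theirs. The processed pseudogene Gm12671 (4:91851668–91852669), 100% identical to Gapdh over the aligned part, held 1324 and 1110 counts in replicates 1 and 2, against 56 and 51 for Gapdh, and Gm12033 (701 and 702), Gm5559 (693 and 550) and Gm7336 (456 and 416) followed. Gm15459 held 1290 and 1236 counts beside 1364 and 1432 for its parent Hspa8, a chaperone, and Gm10123 held 416 and 654 beside 469 and 702 for the peptidyl-prolyl isomerase gene Ppia.

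Antisense transcripts made up 3.45% and 4.77% of mouse counts (4.11 ± 0.935%, n = 2). Of the 20 unannotated loci with the most counts, 18 lay opposite an annotated gene. Of these 20, 5 lay on the minus strand between Meg3 and Mirg (12:109541001–109749460), a maternally expressed cluster of plus-strand RNAs, with 770 and 1435 counts in sum. Of the replicate 2 counts, 244 were on a locus beside Rtl1 (12:109600820–109602914) where replicate 1 had counts named Rtl1, and the other 4 loci held 770 and 1191. Of these, 3 lay opposite an annotated gene and 1 (12:109581013–109584432, 372 and 426 counts) opposite none. Among spike-ins, 0 had counts on both strands, and ERCC-00009 (166 and 105), ERCC-00116 (93 and 27), ERCC-00099 (2 and 4) and ERCC-00059 (1 and 0) had counts on the minus strand only.

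Epidermal transcripts were almost absent from replicate 1. The added keratinocyte and hair follicle lists hold 38 members, and the 30 with at least 3 counts in sum are called measured. Members near 0 counts in replicate 1 reach that minimum only through replicate 2. Skin in the replicate 2 dissection predicted that further skin and hair genes are higher there, and 100% of 30 measured members of the 2 added lists were (19 of the keratinocyte list with 19 and 289 counts, median log2 ratio 3.87; 11 of the hair follicle list with 2 and 292, median 5.01), as were the melanocyte genes Pmel (5 and 14 counts) and Dct (3 and 10), though the unmeasured Mlana and Tyr had 1 and 0 counts each and Tyrp1 0 and 1. Reads shared between keratin paralogs fail to account for it, since members that are not keratins had a median of 3.66, and so does gene assignment, since replicate 1 held 0.425% of the replicate 2 counts at the 6 positions (4 and 941). Skin in the dissection is thus the explanation these tests favour over the others tested, and the fixed and added epidermal and hair markers alone held 0.149% of replicate 2 counts. Carry-over from another library would give the same values and was not tested here.

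The ratio between the libraries went down with transcript length. Length bias in preparation or sequencing would act on spike-ins too, but their slope per doubling of length was −0.128 (34 spike-ins of 274 to 1994 nt, 95% interval −0.41 to 0.15, two-sided permutation p 0.410), beside −0.10 for 1667 mouse genes of those lengths and −0.27 for all 5872, so the question stays open. More partial RNA in replicate 2 also stays open, with the ISM share on genes over 4 kb higher by 0.242 points (17.8% and 18.1%, with overlapping intervals). Within these, it was higher from 4 to 8 kb (17.3% and 17.7%) and lower over 8 kb (25.1% and 23.2%), with separate 95% intervals in each bin. For Myh4 the upper bound of the log2 ratio (−1.48) lay below the lowest bound of the other myosin genes with at least 100 counts (Myh2, −1.19), a difference of −0.283. By counting error, Myh4 thus fell further than these genes. The bounds leave out the spread between mice, and Myh4 was chosen for its low ratio. Whether length is the whole cause of its low level therefore stays open.

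Some of the largest differences at single genes came from how structures were named. Of the 10 genes with the largest ratios lower in replicate 2, 2 (Pitpna and Rtl1) came to under 0.5 by position, which argues against gene assignment as the main cause, and 8 kept an absolute log2 ratio of at least 1. That number tells nothing of RNA or library yield, since the genes were chosen for their ratio and their counts by position were the same, so this explanation stays open. Among the 10 genes with the smallest adjusted p for leading share, 6 had a difference of at least 10 points, and 5 of these shrank to less than 1 part in 2 when the class of either library was used, and Pmp22 (−16.6 points) did not. Of all 25 called genes, 15 were called in that setting too.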
